A study of Mus musculus with 6 samples.

How the data were processed

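RNA was measured by bulk sequencing in 6 libraries of mouse bladder tumor organoids, which are small 3-dimensional cultures grown from tumor cells. Per the labels, 3 libraries came from organoids treated with SRT1720 and 3 from organoids given vehicle, from C57BL/6 mice. Groups and replicate numbers were taken from the sample titles. No label states that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical in part. Libraries of a group were also checked for a library deposited more than once: the median chi-square per degree of freedom over genes was 14.9 to 32.5, so no pair agreed within sampling noise and each library was counted as 1 replicate.

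The authors deposited one table of TPM values, in which reads are scaled by gene length and library, with 51912 Ensembl gene IDs and one column per library, and the unit is taken from the deposited table's own name. STAR 2.6.0 and GRCm38 are named in the submitters' processing notes, with no role or order. The counting program, gene length definition, annotation release and treatment of reads that map to several places are not given in the sources used here. The deposited TPM columns summed to between 161231 and 171577, whereas TPM columns sum to 1000000 by definition. Gene names, gene types and positions came from GENCODE mouse release M21 on GRCm38, which matched 51719 of the IDs, and 193 IDs were not matched. In all 6 libraries, 24199 IDs were at 0. Annotated pseudogenes held 44.0% to 46.9% of the summed values in each library and protein-coding genes 48.7% to 51.3%, so genes with near-identical copies are uncertain.

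Each deposited TPM value multiplied by a whole-number gene length fell on multiples of one step per library, which is what 1 read is worth. A length was found for 27712 of 27713 IDs above 0, and 100% of their values above 0 came out as whole reads within 0.01. A length was accepted only where every value above 0 came out near a whole read, so that 100% follows from the search. The smallest such length was kept, which can understate the reads of low genes. In a test on simulated data, all read counts were recovered for 98.9% of 3041 genes with a mean of at least 20 reads. The recovered depth was 18249099 to 22839128 reads per library, and 1 read on a 1 kb gene was worth 0.017 to 0.0212 TPM. The denominator behind each library's values was 2.572 to 2.583 times its recovered reads, so the deposited values were scaled like reads per kilobase per library depth and not like TPM by its definition. They are called TPM because the deposited table names them so, and were compared between libraries as deposited and read as relative levels. The length recovered for some genes, such as Gapdh and Tpi1, exceeded the span of the gene on GRCm38. Levels of different genes, the shares by gene type and the filter on low values therefore depend on lengths whose definition is not given.

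The test for each gene used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend) on log2(TPM + 1), for the 9287 genes with a mean of at least 1 TPM, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, and SRT1720 minus Vehicle is positive where SRT1720 was higher. In data simulated from these genes with the spread seen here, this test called 46% of genes changed by a log2 of 1 and 79% of genes changed by a log2 of 2, and called 4 unchanged genes. The simulated genes varied independently, unlike the real ones, so these shares may not carry over to the real data. Permutation tests of single genes were exact and two-sided, and 3 libraries against 3 cannot give a p below 0.1. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

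Before the data were examined, 31 gene lists were fixed. They covered HIF target genes, HIF pathway components, glycolysis enzymes, sirtuins and NAD metabolism, p53 target genes, DNA replication and S phase, mitosis and G2/M phase, MYC and ribosome biogenesis, cholesterol biosynthesis, fatty acid synthesis, fatty acid oxidation, lysosome and autophagy, the ATF4 integrated stress response, endoplasmic reticulum chaperones, the NRF2 oxidative stress response, oxidative phosphorylation, mitochondrially encoded genes and cytosolic ribosomal proteins. The others were NF-kB and inflammatory cytokines, the interferon response, epithelial to mesenchymal transition, basal and luminal urothelial markers, keratinization and squamous differentiation, the AhR xenobiotic response, immediate early genes, the heat shock response, and markers of fibroblasts, leukocytes, endothelium and smooth muscle. Lists with at least 5 measured genes, 27 in all, were tested with limma's camera, which compares a list with all other genes, at its preset correlation of 0.01, and also with an estimated correlation and with fry. In a simulation with 1 list shifted by a log2 of 1, camera at the preset correlation ranked that list first and called 3 lists. In simulations of 20 unchanged data sets with independent genes it called a list in 1. Genes of the real lists were not independent, with estimated correlations of up to 0.86 (ATF4), so that rate does not carry over to them.

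The rule for named genes, also fixed before the data were examined, took the genes past the adjusted threshold without overlap between groups, of which there were none. It then took the 10 genes with the smallest p, given as not passing, and up to 4 members with the smallest p from each list described. It also took the 3 genes of highest mean TPM in each group and 12 genes of the SIRT1 and HIF pathways whatever their values. Members are given for 16 lists, the 12 past the threshold and the HIF target, HIF component, sirtuin and p53 lists. Which lists to describe by member was decided after the results were seen.

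Alternatives planned before the data were examined changed the pseudocount, the filter, the scaling, the variance model and the library weights, added the replicate number as a block, left out each library in turn and used the other list tests. After seeing the data, 4 were added: voom on the recovered reads, protein-coding nuclear genes only after rescaling, leaving out SRT1720 1 and Vehicle 2, chosen because they stood apart in the level of Krt5 and on the first principal component, 1 in each group, and removal of a gene length and GC trend from each library. SRT1720 1 and Vehicle 2 were at −27.5 and −35.8 on the first principal component. SRT1720 3 and Vehicle 3 lay about as far out on the other side, at 33.4 and 27.4, and were kept. All 6 deposited columns were used.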

Results

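Gene expression was profiled in mouse bladder tumor organoids treated with SRT1720, a small molecule described as an activator of the deacetylase SIRT1, and in organoids given vehicle. Each group had 3 libraries. The depth recovered from the TPM values was 20991611, 21821567 and 21332622 reads for SRT1720 1, 2 and 3, and 22839128, 18249099 and 20019081 reads for Vehicle 1, 2 and 3. Between 9002 and 9289 genes reached 1 TPM in a library. Values below are in the unit that the deposited table names TPM, although each library was scaled by its depth and its column does not sum as TPM does. They are means ± SD over the 3 libraries of a group unless stated otherwise.

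The libraries differed strongly within each group. Krt5, a basal epithelial keratin, was at 16.4, 616 and 1120 TPM in SRT1720 1, 2 and 3 and at 425, 9.61 and 741 TPM in Vehicle 1, 2 and 3. Krt18, a keratin of luminal epithelium, was highest in SRT1720 1 and Vehicle 2, at 226 and 162 TPM, and lay between 25.3 and 57.6 TPM in the other libraries. Genes on chromosome 3 were lower in SRT1720 3 and Vehicle 3, with medians of −0.42 and −0.44 (log2) against their group means, while the other 4 libraries lay between 0.14 and 0.29. Krt5, Krt18 and the chromosome medians are described because of their values and were not chosen in advance. Of the markers of other cell types, 0 of 15 endothelial, 1 of 10 smooth muscle, 2 of 16 fibroblast and 3 of 22 leukocyte genes reached a mean of 1 TPM. The highest mean in these 4 lists was 10.1 TPM, in the leukocyte list. The summed mitochondrial ribosomal RNA values were 702 TPM in SRT1720 3 and 1562 TPM in Vehicle 3, against 135 to 198 TPM in the other libraries, so neither group held all the high ones.

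**Figure D1:**
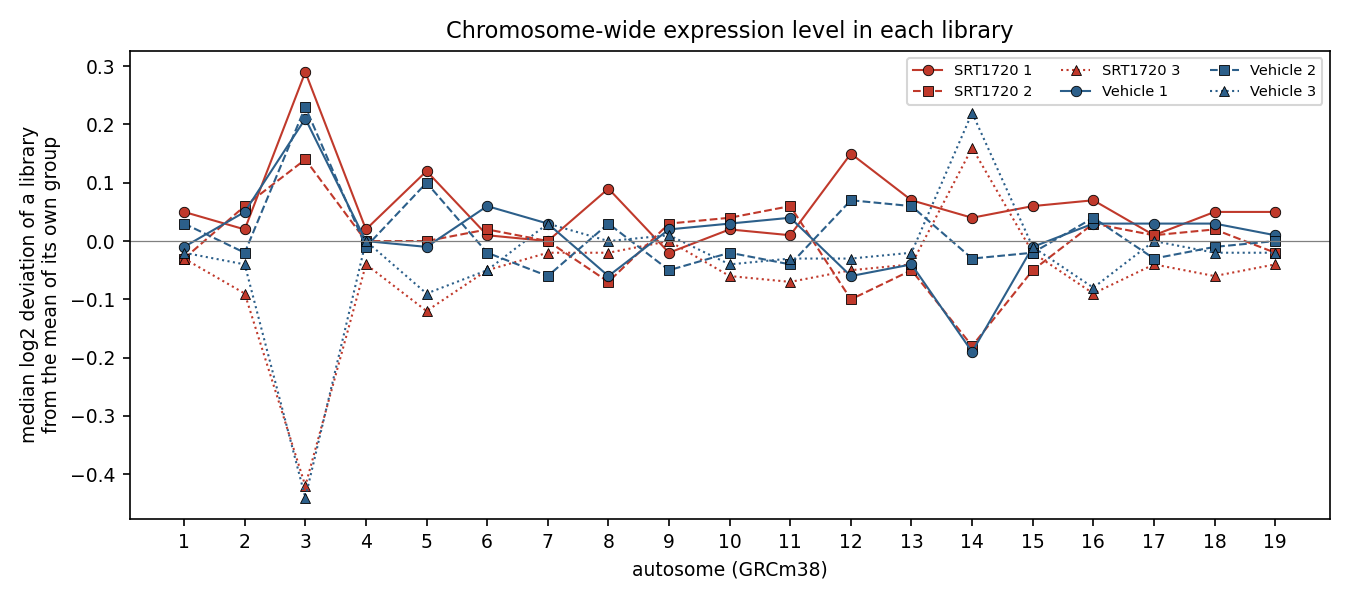
Median log2 deviation of each library from the mean of its own group, for the protein-coding genes of each autosome. On chromosome 3, SRT1720 3 and Vehicle 3 lie at −0.42 and −0.44 and the other 4 libraries lie between 0.14 and 0.29.

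The question named in the series title is whether SRT1720 acts through SIRT1 and the hypoxia-inducible factors (HIF), transcription factors that drive the response to low oxygen. The values here are mRNA levels only, so they do not show SIRT1 activity or the amount of HIF proteins. Sirt1 mRNA was at 1.05 ± 0.25 TPM with SRT1720 and 0.724 ± 0.25 TPM with vehicle, with overlapping libraries (exact permutation p = 0.2). Hif1a, the oxygen-regulated subunit, was at 18.9 ± 5.74 against 22.2 ± 10.8 TPM. Epas1 (HIF-2α) was at 4.51 ± 1.21 against 4.75 ± 1.58 TPM, and Arnt, their dimerization partner, was at 1.62 ± 0.41 against 2.37 ± 0.92 TPM. Vhl, the ubiquitin ligase subunit that targets HIF for degradation, was at 4.27 ± 0.93 against 3.93 ± 0.89 TPM. Rbx1 and Egln2, also in the list of HIF pathway components, were at 15.3 ± 1.12 against 12.8 ± 2.32 TPM and at 5.96 ± 1.27 against 4.8 ± 0.77 TPM. Egln3 was at 27.5 ± 12.8 against 17.0 ± 11.6 TPM. In the list of HIF pathway components, 8 of 14 measured members had log2 fold changes above 0 and the median was 0.03 (camera adjusted p = 0.891). The median log2 fold change of HIF pathway components turned to −0.02 without SRT1720 1, −0.06 without Vehicle 3, −0.02 with median-of-ratios scaling and −0.0044 with quantile normalization, and was 0.15 without Vehicle 2 and 0.25 at a mean of at least 5 TPM.

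Among HIF target genes, Vegfa, an angiogenic growth factor, was at 10.8 ± 4.33 TPM with SRT1720 and 17.8 ± 8.05 TPM with vehicle. The glucose transporter gene Slc2a1 was at 13.3 ± 5.56 against 13.1 ± 4.38 TPM. The mean TPM of Pdk1, which encodes a kinase that inhibits pyruvate dehydrogenase, was 3.46 ± 1.70 against 1.81 ± 0.65, and that of Bnip3, a mitophagy receptor gene, 4.21 ± 2.36 against 3.60 ± 1.34. Car9 was at 0.989 ± 1.26 against 0.743 ± 0.67 TPM and stayed below the filter, as did Sirt1. Mxi1, at 3.90 ± 0.05 against 5.54 ± 0.69 TPM, and Higd1a, at 4.04 ± 1.16 against 2.70 ± 0.24 TPM, were the HIF targets whose libraries did not overlap between groups, one lower and one higher. No HIF target passed limma's test, over all genes or adjusted over the list alone. The fixed HIF target list does not cover HIF targets in general. It leaves out glycolytic genes such as Ldha and Pgk1, which are tested among the glycolysis enzymes below. It shares Vegfa, Ddit4 and Stc2 with the ATF4 integrated stress response list, and Egln1 and Egln3 with the HIF pathway components. Of 24 measured HIF targets in the list, 9 had log2 fold changes above 0 and 15 below, with a median of −0.05. The list did not pass (camera adjusted p = 0.618, and adjusted p = 0.952 with an estimated correlation). The median depended on single libraries: it was 0.067 without SRT1720 1, 0.012 without SRT1720 2 and 0.12 without Vehicle 3, and −0.21 without SRT1720 3, where the list passed (adjusted p = 0.0351). At a mean of at least 5 TPM the median log2 fold change of HIF target genes was −0.22, and without both SRT1720 1 and Vehicle 2 it was 0.041.

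**Figure D2:**
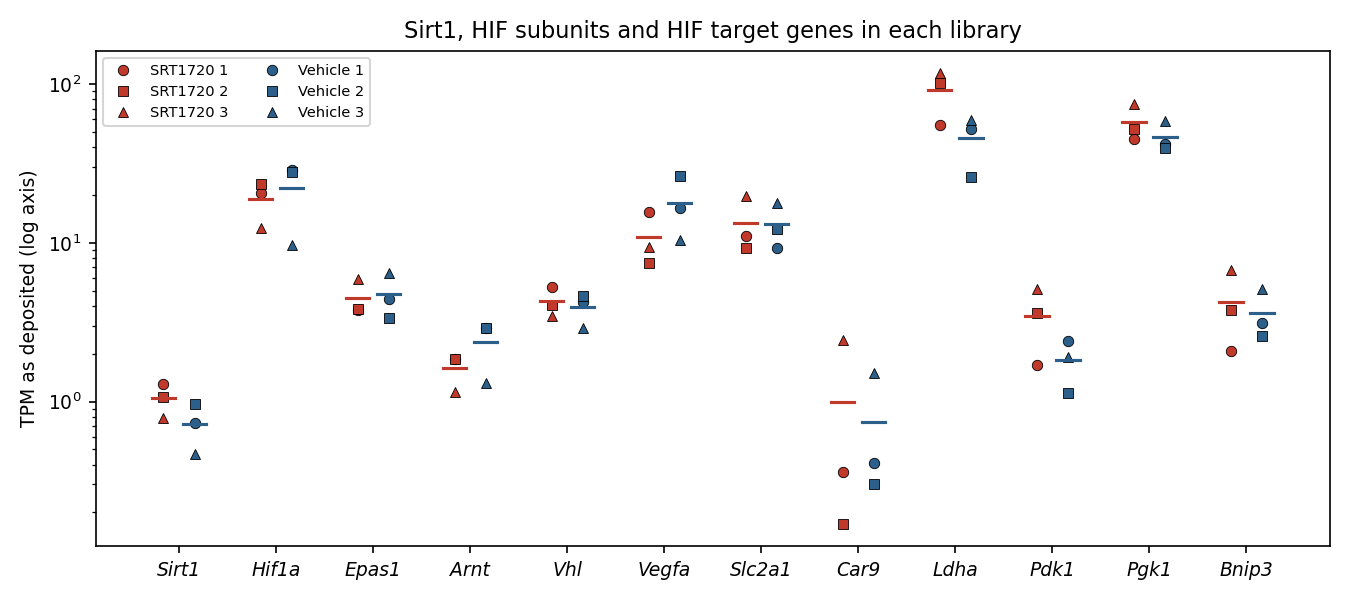
TPM as deposited (log axis) of Sirt1, HIF subunits and HIF target genes in each of the 6 libraries, with bars at the group means. Points of both groups overlap for all 12 genes, for example Hif1a at 12.4 to 23.5 TPM with SRT1720 and 9.73 to 28.8 TPM with vehicle.

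In the list of sirtuins and NAD metabolism, 7 of 21 genes were measured, without Sirt1, which stayed below the filter. Their median log2 fold change was 0.12 (camera adjusted p = 0.767). The median log2 fold change of sirtuins and NAD metabolism was 0.07 without SRT1720 1 or SRT1720 3, 0.05 without Vehicle 1, 0.06 without Vehicle 2 and 0.0045 with no filter on low values, and −0.02 without both SRT1720 1 and Vehicle 2. Nadk, an NAD kinase gene, was at 12.1 ± 1.18 against 9.68 ± 1.01 TPM, and Sirt7 at 1.71 ± 0.34 against 1.34 ± 0.49 TPM. Sirt2 was at 1.88 ± 0.22 against 2.13 ± 0.34 TPM, and Nampt, the rate-limiting enzyme gene of NAD salvage, at 8.94 ± 1.55 against 10.1 ± 0.31 TPM.

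Over all genes, the largest separations between groups relative to their spread were in Dhx9, an RNA helicase gene, at 9.86 ± 0.99 TPM with SRT1720 and 2.29 ± 0.54 TPM with vehicle, and in Mt1. Mt1, a metal-binding metallothionein gene, was at 78.7 ± 27.4 against 10.7 ± 1.84 TPM. Rrm2, which encodes a subunit of ribonucleotide reductase, was at 41.2 ± 6.87 against 15.2 ± 0.91 TPM. Hnrnpm, an RNA-binding protein gene, was at 20.9 ± 1.35 against 9.41 ± 0.55 TPM. Nr1d1, a repressor of the circadian clock, was at 2.47 ± 0.54 against 10.3 ± 2.93 TPM, and Rab6b at 0.407 ± 0.13 against 1.90 ± 0.18 TPM. Eef1akmt1 was at 8.79 ± 0.48 against 3.17 ± 0.15 TPM, Dhrs4 at 6.29 ± 1.30 against 1.62 ± 0.20 TPM. The processed pseudogene Gm9761 was at 144 ± 23.5 against 54.8 ± 6.02 TPM, and mt-Nd3, a mitochondrially encoded subunit of respiratory complex I, at 588 ± 125 against 207 ± 33.5 TPM. These are the 10 genes with the smallest p, and in each the 3 SRT1720 libraries lay on one side of the 3 Vehicle libraries, yet none passed limma's adjusted test (adjusted p = 0.132 to 0.155). The log2 fold changes were 1.73 (SE 0.17) for Dhx9, 2.73 (SE 0.27) for Mt1 and −1.68 (SE 0.23) for Nr1d1.

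On GRCm38, Dhx9 (ENSMUSG00000042699) lies on chromosome 1 from 153455758 to 153487660, Mt1 (ENSMUSG00000031765) on chromosome 8 from 94179082 to 94180327, Rrm2 (ENSMUSG00000020649) on chromosome 12 from 24708241 to 24714146. Hnrnpm (ENSMUSG00000059208) lies on chromosome 17 from 33646233 to 33686860 and Nr1d1 (ENSMUSG00000020889) on chromosome 11 from 98767932 to 98775333. Rab6b (ENSMUSG00000032549) lies on chromosome 9 from 103111787 to 103185276, Eef1akmt1 (ENSMUSG00000021951) on chromosome 14 from 57549597 to 57571612. Dhrs4 (ENSMUSG00000022210) lies on chromosome 14 from 55478758 to 55490340, Gm9761 (ENSMUSG00000034437) on chromosome 3 from 116560935 to 116561426 and mt-Nd3 (ENSMUSG00000064360) on the mitochondrial genome from 9459 to 9806. The lowest recovered depth behind any of these values was 101 reads, for Rab6b.

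**Figure D3:**
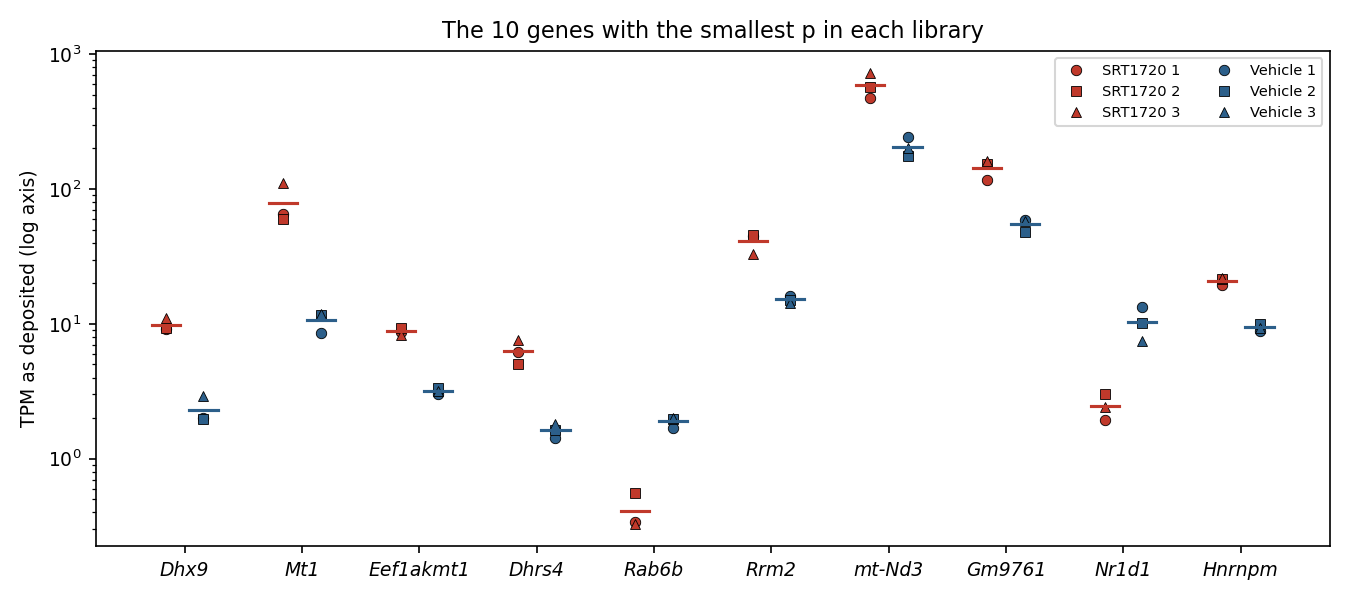
TPM as deposited (log axis) of the 10 genes with the smallest p in each of the 6 libraries, with bars at the group means. In each gene the groups do not overlap, for example Mt1 at 60.1 to 110 TPM with SRT1720 and 8.56 to 11.8 TPM with vehicle.

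By limma with Benjamini-Hochberg adjustment, 0 genes were called higher and 0 lower with SRT1720 among 9287 tested, and so 0 were called as changed at least 2-fold. At an unadjusted p under 0.05 there were 1153 genes, 730 higher and 423 lower, of which 92 differed by at least a log2 of 1. The groups did not overlap in 1845 genes (19.9%, where chance gives 10% if all libraries are exchangeable), 1125 higher and 720 lower. Each library resembled one library of the other group, so that 10% may not hold here. The fit did not use this resemblance, so the differences between unlike libraries of a group counted as spread. That 0 genes passed therefore does not show that no gene changed. Voom on the recovered reads also gave 0 genes, and 1125 at an unadjusted p under 0.05. Without SRT1720 2 the unadjusted count was 523.

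Of 27 gene lists, 12 passed camera at its preset correlation and 0 with an estimated correlation. All 30 measured genes of the DNA replication and S phase list had log2 fold changes above 0, with a median of 0.47, and 18 did not overlap between groups. Besides Rrm2, Ccne1 and Ccne2, the cyclins of entry into S phase, were at 6.41 ± 0.56 against 3.26 ± 0.82 TPM and at 2.40 ± 0.40 against 1.06 ± 0.36 TPM. Uhrf1, a factor that maintains DNA methylation at replication, was at 20.1 ± 2.99 against 11.7 ± 0.37 TPM. The list rose relative to other genes (camera adjusted p = 4.31e-11, and adjusted p = 0.785 with an estimated correlation), and 7 members passed when adjusted over the list alone, all higher, while 0 passed over all genes.

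The MYC and ribosome biogenesis list also rose, with 28 of 29 members above 0 and a median log2 fold change of 0.41 (camera adjusted p = 2.65e-08, and adjusted p = 0.785 with an estimated correlation). Rrp12 was at 5.73 ± 0.65 against 2.44 ± 0.43 TPM, Bop1 at 15.3 ± 4.09 against 7.01 ± 2.24 TPM. Nolc1 was at 28.1 ± 3.43 against 17.8 ± 3.50 TPM and Ncl, which encodes nucleolin, at 41.1 ± 1.97 against 27.7 ± 2.85 TPM. Adjusted over the list alone, 1 member passed.

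Genes of cholesterol biosynthesis rose as a list, with all 23 measured members above 0 and a median log2 fold change of 0.64 (camera adjusted p = 1.08e-05, and adjusted p = 0.856 with an estimated correlation). Cyp51 was at 17.9 ± 6.63 against 7.18 ± 1.56 TPM, Idi1 at 18.9 ± 9.49 against 6.25 ± 3.62 TPM. Msmo1 was at 10.1 ± 2.34 against 5.36 ± 1.65 TPM and Ebp at 4.78 ± 0.61 against 3.07 ± 0.78 TPM. Of the list, 3 members did not overlap between groups. None passed when adjusted over the list alone. The median was 0.96 without SRT1720 1 and 0.42 without Vehicle 2.

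Cytosolic ribosomal protein genes fell as a list, with 30 of 37 members below 0 and a median log2 fold change of −0.22 (camera adjusted p = 2.92e-05, and adjusted p = 0.856 with an estimated correlation). Rpl5 was at 19.3 ± 2.13 against 29.0 ± 2.97 TPM, Rps15 at 272 ± 12.7 against 360 ± 11.9 TPM. Rps19 was at 26.7 ± 1.23 against 38.2 ± 3.23 TPM and Rpl32 at 138 ± 2.49 against 183 ± 18.1 TPM. These genes have many processed pseudogene copies, so their levels are uncertain where reads could be split. Genes of lysosome and autophagy fell as well, with 27 of 32 members below 0 and a median of −0.28 (camera adjusted p = 2.92e-05, and adjusted p = 0.785 with an estimated correlation). Gabarapl1 and Map1lc3a, which encode autophagosome membrane proteins, were at 5.98 ± 2.01 against 12.6 ± 1.89 TPM and at 7.24 ± 0.90 against 12.6 ± 2.25 TPM. Psap, a precursor of lysosomal activator proteins, was at 50.5 ± 0.78 against 69.6 ± 2.77 TPM, and Lamp2, a lysosomal membrane protein gene, at 8.06 ± 0.21 against 11 ± 0.64 TPM. No member of either list passed when adjusted over the list alone. The median log2 fold change of cytosolic ribosomal proteins was −0.39 without Vehicle 2, also −0.39 without both SRT1720 1 and Vehicle 2, and −0.12 without Vehicle 3, and the lysosome median −0.16 without SRT1720 3 and −0.17 without Vehicle 2.

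**Figure D4:**
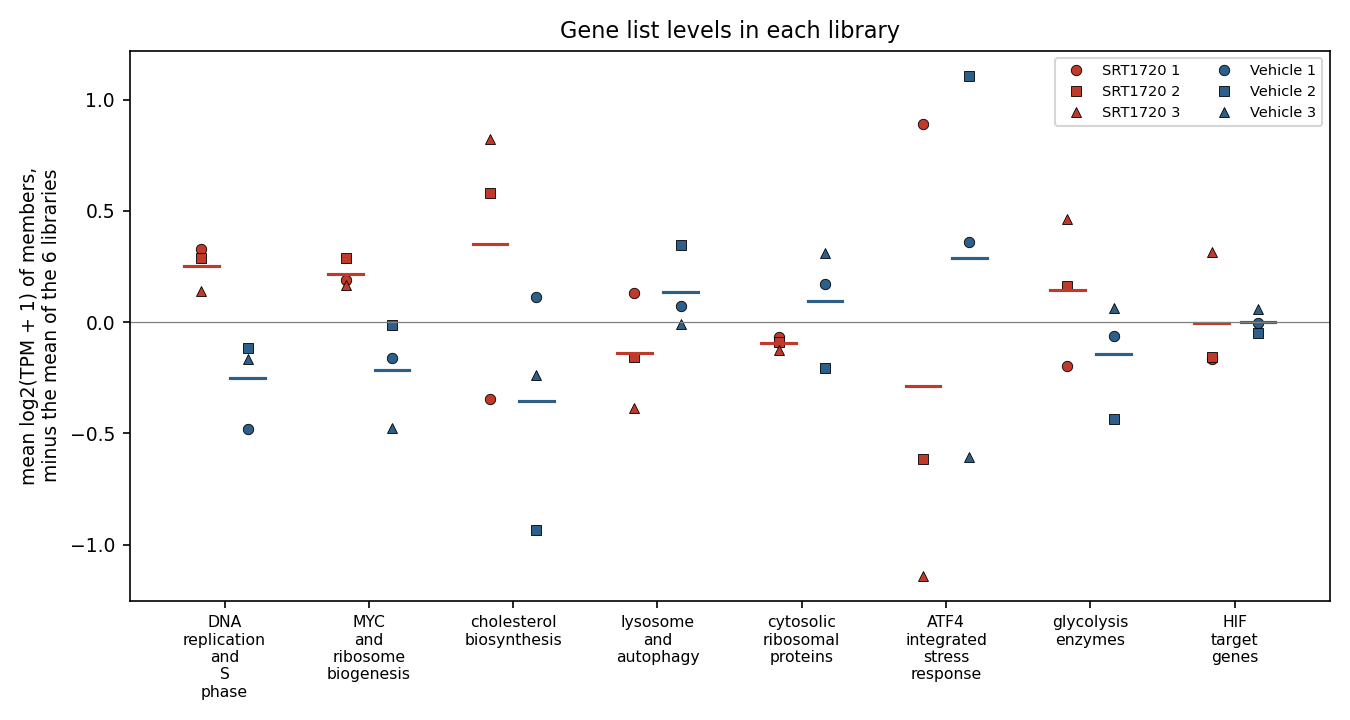
Mean log2(TPM + 1) of the measured members of 8 gene lists in each library, minus the mean over the 6 libraries, with bars at the group means. For DNA replication and S phase the SRT1720 libraries lie between 0.141 and 0.331 and the Vehicle libraries between −0.479 and −0.114.

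The lists of the ATF4 integrated stress response and of endoplasmic reticulum chaperones fell at the preset correlation, with overlapping libraries of both groups and an adjusted p = 0.856 for each with an estimated correlation. In the ATF4 integrated stress response list, which holds genes induced by amino acid and protein folding stress, 29 of 31 members were below 0 with a median log2 fold change of −0.42 (camera adjusted p = 9.31e-04). Asns was at 23.1 ± 14.1 against 36.7 ± 11.5 TPM, Ddit3 at 6.87 ± 7.53 against 15.1 ± 10.03 TPM and Aldh1l2 at 2.14 ± 1.91 against 4.93 ± 2.69 TPM. In this list 0 members were free of overlap. The ATF4 list passed in 18 of 20 other settings of the preset camera test, and did not pass without SRT1720 3 (median −0.12, adjusted p = 0.189) or without Vehicle 2 (median −0.22, adjusted p = 0.270). The median log2 fold change of ATF4 integrated stress response genes was −0.98 without SRT1720 1, −0.95 without Vehicle 3 and −0.71 with library weights. Endoplasmic reticulum chaperones had 20 of 22 members below 0 and a median of −0.30 (camera adjusted p = 0.0024, and adjusted p = 0.856 with an estimated correlation). Pdia6 was at 18.0 ± 2.88 against 32.0 ± 11.8 TPM, Sdf2l1 at 10.03 ± 0.57 against 21.3 ± 12.9 TPM. Hsp90b1 was at 18.1 ± 4.22 against 31.4 ± 12.6 TPM and Edem1 at 2.08 ± 0.35 against 3.11 ± 0.95 TPM. The chaperone list passed in 18 of 20 other settings, and its call was lost without Vehicle 2 (median 0.023, adjusted p = 0.971) and without both SRT1720 1 and Vehicle 2 (median −0.03, adjusted p = 0.708). Without Vehicle 3 its median was −0.60.

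The mitosis and G2/M phase list rose, with 31 of 32 members above 0 and a median of 0.32 (camera adjusted p = 0.0128, and adjusted p = 0.856 with an estimated correlation). Birc5 was at 11.4 ± 0.87 against 6.98 ± 2.42 TPM, Nuf2 at 4.33 ± 0.69 against 2.99 ± 0.56 TPM. Ccnb1, the mitotic cyclin gene, was at 7.55 ± 0.72 against 4.89 ± 2.33 TPM and Kif11 at 15.6 ± 0.98 against 12.1 ± 3.25 TPM. The mitosis list passed in 16 of 20 other settings, and its call was lost without SRT1720 2 (median 0.18, adjusted p = 0.133), without Vehicle 2 (median 0.031, adjusted p = 0.995), without both SRT1720 1 and Vehicle 2 (median 0.14, adjusted p = 0.128) and at a mean of at least 5 TPM (median 0.34, adjusted p = 0.0851). Without Vehicle 1 the median was 0.53. In the epithelial to mesenchymal transition list, which fell, 11 of 13 members were below 0 with a median of −0.36 (camera adjusted p = 0.0185, and adjusted p = 0.785 with an estimated correlation). Ccn1 was at 10.03 ± 12.3 against 49.3 ± 16.8 TPM, Thbs1 at 2.52 ± 1.66 against 5.42 ± 2.58 TPM. Mmp14 was at 4.96 ± 0.42 against 6.70 ± 1.13 TPM and Itga5 at 1.38 ± 0.38 against 1.995 ± 0.37 TPM. The transition list passed in 16 of 20 other settings, and its call was lost without SRT1720 3, where the median stayed at −0.30 (adjusted p = 0.0634), without Vehicle 1, where it was −0.05 (adjusted p = 0.123), at a mean of at least 5 TPM (median −0.32, adjusted p = 0.159) and with library weights (median −0.26, adjusted p = 0.077). The median log2 fold change of epithelial to mesenchymal transition genes was −0.78 without SRT1720 2, −0.59 without Vehicle 3, −0.21 with no filter on low values and −0.82 by voom.

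Of the 13 mitochondrially encoded genes, 10 were above 0 and 3 below, with a median log2 fold change of 0.52 (camera adjusted p = 0.0185, and adjusted p = 0.856 with an estimated correlation). Adjusted over the list alone, 4 members were higher and 1 lower, and fry's mixed test, which asks whether members change in either direction, gave an adjusted p of 0.00199. Beside mt-Nd3, mt-Nd2 was at 797 ± 219 against 384 ± 124 TPM and mt-Cytb at 1355 ± 200 against 733 ± 247 TPM. In contrast, mt-Co1, a subunit of cytochrome c oxidase, was at 2707 ± 253 against 4433 ± 220 TPM. These genes may share reads with nuclear copies such as Gm29216, which was at 2093 ± 124 against 3353 ± 427 TPM, so their levels are uncertain. The list passed camera in 17 of 19 other settings, and the call was lost without SRT1720 3 (median 0.31, adjusted p = 0.102) and without Vehicle 1 (median 0.39, adjusted p = 0.0707).

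Glycolysis enzymes rose as a list, with 12 of 16 members above 0 and a median of 0.29 (camera adjusted p = 0.0469, and adjusted p = 0.856 with an estimated correlation). Ldha was at 91.2 ± 32.2 against 45.7 ± 17.6 TPM, Pgk1 at 57.5 ± 15.9 against 46.7 ± 10.3 TPM. Tpi1 was at 65.5 ± 9.63 against 44.8 ± 5.14 TPM, Gapdh at 36.1 ± 3.95 against 25.5 ± 3.74 TPM and Pfkl at 11.3 ± 5.37 against 5.62 ± 1.63 TPM. Glycolysis passed in 10 of 20 other settings, and its call was lost without SRT1720 3 (median 0.09, adjusted p = 0.566), Vehicle 1 (median 0.25, adjusted p = 0.0683) or Vehicle 2 (median 0.17, adjusted p = 0.469). It was also lost with both other pseudocounts, no filter, a mean of at least 5 TPM, median-of-ratios scaling, library weights and the length and GC trend removed, at medians of 0.23 to 0.29 (adjusted p = 0.0501 to 0.0973). Nuclear genes of oxidative phosphorylation rose with 32 of 40 members above 0 and a median of 0.13 (camera adjusted p = 0.0493, and adjusted p = 0.856 with an estimated correlation). Ndufa5 was at 11.9 ± 1.74 against 7.96 ± 1.003 TPM, Uqcrc1 at 14.6 ± 0.72 against 11.5 ± 1.44 TPM. Atp5o was at 8.64 ± 1.36 against 6.64 ± 0.69 TPM and Atp5g1 at 1.998 ± 0.22 against 1.30 ± 0.54 TPM. Oxidative phosphorylation passed in 8 of 20 other settings, and its call was lost without SRT1720 2 (median 0.09, adjusted p = 0.17) and without Vehicle 3 (median 0.08, adjusted p = 0.666). It was also lost with both other pseudocounts, a mean of at least 5 TPM, both other scalings and library weights. The same held with the replicate block, voom, protein-coding nuclear genes only and the length and GC trend removed. Medians in these settings were 0.08 to 0.16 (camera adjusted p = 0.0503 to 0.194). Without Vehicle 1 the median was 0.26.

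The p53 target genes had a median of −0.20 with 13 of 21 members below 0 and did not pass (camera adjusted p = 0.0577, and adjusted p = 0.856 with an estimated correlation). The list passed without SRT1720 1 (median −0.34, adjusted p = 0.0191), Vehicle 1 (median −0.14, adjusted p = 0.0163) or Vehicle 3 (median −0.29, adjusted p = 0.0359), and did not without SRT1720 2 (median −0.14), SRT1720 3 (median −0.12) or Vehicle 2 (median −0.09). The p53 list also passed with the replicate number as a block (median −0.199, camera adjusted p = 0.0462), although these numbers did not pair the samples. Trp53inp1 was at 0.716 ± 0.45 against 2.72 ± 2.37 TPM, Plk2 at 21.3 ± 7.71 against 37.5 ± 17.3 TPM. Bbc3 was at 1.09 ± 0.76 against 2.07 ± 0.94 TPM and Zmat3 at 0.773 ± 0.22 against 1.45 ± 0.99 TPM. Of the lists with no call, fatty acid oxidation had a median log2 fold change of −0.09 (camera adjusted p = 0.152), NRF2 oxidative stress −0.08 (0.155), fatty acid synthesis 0.28 (0.261), immediate early genes −0.14 (0.43), the AhR xenobiotic response −0.59 (0.462) and NF-kB and inflammatory cytokines 0.26 (0.53). The interferon response was at 0.01 (camera adjusted p = 0.783), the heat shock response at 0.11 with a mean of −0.02 (0.89), luminal urothelial markers at 0.15 (0.891) and basal urothelial markers at 0.43 (0.919). Keratinization and squamous differentiation had a median of 0.15 although camera's direction was down (adjusted p = 0.913). The AhR list had 5 measured members, 2 above 0 and 3 below, and the median log2 fold change of AhR xenobiotic response genes was −0.11 without Vehicle 1, −0.96 without Vehicle 3 and −0.0025 with no filter on low values. The median of fatty acid synthesis was 0.61 without Vehicle 1 and 0.05 without Vehicle 2, and that of NRF2 was −0.24 without Vehicle 2 and −0.0041 without Vehicle 1. The medians of fatty acid oxidation, immediate early genes, NF-kB, interferon, heat shock, keratinization and both lists of urothelial markers crossed 0 when single libraries were left out.

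In all, 12 of 27 lists passed camera at its preset correlation, 7 higher and 5 lower, against 0 with an estimated correlation, 0 by fry and 3 by fry's mixed test. The 3 were the mitochondrially encoded genes, DNA replication and S phase (adjusted p = 0.0296) and MYC and ribosome biogenesis (adjusted p = 0.0415). By mean TPM, the 3 highest genes with SRT1720 were Gm23935, Gm10925 and Gm28661, and with vehicle mt-Co1, Gm23935 and Gm29216. Gm23935, annotated as a microRNA gene, was at 4595 ± 1279 against 3912 ± 720 TPM. Gm28661, a nuclear copy of mitochondrial genes, was at 2721 ± 128 against 2882 ± 407 TPM. Gm10925, another such copy, was at 2845 ± 414 against 2486 ± 466 TPM. These values are divided by gene length, and Gm23935 spans only 11144125 to 11144181 on chromosome 16. Gm23935 had 9080 to 18311 recovered reads per library, against 202134 to 409999 for mt-Co1. Its rank thus depends on its short length and does not show an abundant microRNA transcript.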

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

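Of the alternatives, voom on recovered reads, protein-coding nuclear genes only, leaving out SRT1720 1 and Vehicle 2, and removal of a length and GC trend were chosen after the data were seen. Across all alternatives, 0 genes passed the adjusted threshold, with a smallest adjusted p between 0.0513 (library weights) and 0.67 (without SRT1720 2). The count at an unadjusted p under 0.05 was 1153, against 2028 with no filter, 498 at a mean of at least 5 TPM, 2056 with library weights and 523 without SRT1720 2; the first 2 test other numbers of genes. DNA replication, MYC, cholesterol, ribosomal protein and lysosome lists kept their call in all 20 settings of the preset camera test, and 0 lists passed with an estimated correlation and 0 with fry. The replicate numbers did not pair the samples: correlations of deviations for the same number were −0.2, −0.26 and 0.79, and neither SRT1720 1 nor SRT1720 2 correlated best with its own number. With the replicate block 0 genes passed, as without it, and 12 lists passed, of which 11 were also called without it; p53 targets were gained (median −0.199, adjusted p = 0.0462) and oxidative phosphorylation was lost (0.055). Leaving out 1 library at a time gave ranges that cross 0 for HIF target genes (−0.2117 to 0.1215), HIF components (−0.0552 to 0.1481), NF-kB (−0.5138 to 0.794), basal markers (−0.4985 to 1.3693), endoplasmic reticulum chaperones (−0.6025 to 0.0228), fatty acid oxidation (−0.1886 to 0.0445), heat shock (−0.0072 to 0.2466), immediate early genes (−0.4233 to 0.2032), interferon (−0.3481 to 0.3037), keratinization (−0.1926 to 0.4046) and luminal markers (−0.028 to 0.2819). The same held for Bnip3 (−0.2206 to 0.4436), Epas1 (−0.2287 to 0.1588), Hif1a (−0.6086 to 0.1355), Slc2a1 (−0.2998 to 0.2314) and Vhl (−0.0576 to 0.2097). Lists without a call passed in single omissions: basal markers without SRT1720 1 (adjusted p = 0.00839) and, in the other direction, Vehicle 2 (0.0446), interferon without Vehicle 1 (0.0163), NF-kB without SRT1720 3 (0.0297), immediate early genes without SRT1720 1 (0.00114), fatty acid synthesis without SRT1720 1 (0.00758) or Vehicle 1 (0.0342), and NRF2 without SRT1720 2, Vehicle 2 or Vehicle 3 (0.037, 0.0412 and 0.0359). Median-of-ratios scaling turned HIF components to −0.0159 and interferon to −0.0256, quantile normalization gave −0.0044, −0.021 and Gm28661 at 0.0351, library weights gave interferon −0.2461, and the length and GC trend gave interferon −0.0154 and Epas1 0.001. Without SRT1720 1 and Vehicle 2, HIF targets were at 0.0411, interferon at −0.1695, NF-kB at −0.047, sirtuins at −0.0213, Hif1a at 0.0199, Slc2a1 at 0.0626 and Gm28661 at 0.0264. There the chaperone and mitosis lists lost their call (adjusted p = 0.708 and 0.128) and immediate early genes passed (0.0136). The cause was not tested for any of these changes. Leaving out 1 library keeps the library of the other group that it most resembled, so it also changes the balance of similar libraries between the groups. Depth was similar in all libraries, at 18249099 to 22839128 reads.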

Other observations

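The following genes outside the fixed lists were picked for their low values with SRT1720 after these were seen, so they carry no test as a group. Nr1d2 was at 3.62 ± 0.35 against 8.11 ± 2.02 TPM (SD over 3 libraries a group), Dbp at 0.323 ± 0.21 against 3.78 ± 3.23 TPM, Tef at 1.40 ± 0.73 against 3.62 ± 0.53 TPM and Per3 at 0.311 ± 0.08 against 0.975 ± 0.29 TPM, each with no overlap between groups. Per1, at 2.87 ± 1.68 against 5.95 ± 2.43 TPM, overlapped, and Per2 was at 0.773 ± 0.27 against 1.62 ± 0.66 TPM. Klhl24 was at 1.22 ± 0.53 against 5.70 ± 1.42 TPM. Per3 stayed below the filter and was not in the main test, and none of the other genes passed limma's adjusted threshold.

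The tests below of same-numbered pairs, of the mitochondrial genes, of the estimated correlation and of the splits by count of genes past the adjusted threshold were chosen or made after the results were seen. Each library resembled one library of the other group: deviations from the group means correlated across genes at 0.72 for SRT1720 1 with Vehicle 2, 0.68 for SRT1720 2 with Vehicle 1 and 0.79 for SRT1720 3 with Vehicle 3. Shared cultures marked by the replicate numbers are argued against, since 1 of 3 same-numbered pairs correlated over 0.1. A length or GC bias is argued against too, as the lowest of the 3 correlations with the closest library was 0.68 once the trend was removed. A candidate explanation is cultures of different origin, each split between SRT1720 and vehicle. In 6 of 6 libraries, window medians along the chromosomes spread beyond all 1000 shuffled gene orders, with chromosome 3 the clearest case. Deviations are taken from the mean of a group's own 3 libraries, so these 6 results are not independent. Shuffling also parts neighbouring genes that vary together for other reasons, so the spread does not decide on origin. The labels name no such origin, and no fit that pairs libraries across numbers was made.

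The lists of DNA replication and MYC were higher and the lysosome list lower with SRT1720 at the preset correlation (adjusted p = 0.785 for each with an estimated correlation), and a length or GC bias is argued against, because the largest adjusted p at the preset correlation was 1.18e-05 after the trend was removed. Genes that vary together among cultures stay open, given that loss of the calls. With 10 splits of the 6 libraries a share under 0.05 cannot be reached, so chance was not decided. The real split gave 12 lists and 5 of 10 splits gave as many, the highest other 17. At an unadjusted p under 0.05, 2 of 10 splits gave as many genes, 1153 against a highest other of 1348. That other split puts SRT1720 1 with Vehicle 2, the library it most resembled. Like the real split, some part each library from the one it most resembled. SRT1720 1 with SRT1720 2 and Vehicle 3 gave 25 such genes and 7 lists. With SRT1720 3 and Vehicle 1 it gave 21 and 10, and with Vehicle 1 and Vehicle 3, 71 and 16. The pairs were seen in these same data, so these counts carry no test. The count of genes past the adjusted threshold was 0 in the real split, a value that all 10 splits reach whatever they give, so the splits do not test it, and the highest other gave 1.

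Among mitochondrial genes, mt-Nd3 was higher and mt-Co1 lower with SRT1720. The nuclear copy Gm28438 had nearly the same recovered reads as mt-Nd3, 2896 to 14044 against 2882 to 13844 per library, so whether reads came from the gene or the copy was not decided. Transcript length is argued against, as the long mt-Nd5 changed by 1.15 more than the long mt-Co1 (log2, SE 0.221). An effect of SRT1720 on mitochondrial transcripts stays open as a hypothesis, untested.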
